A study of Mus musculus with 24 samples.

How the data were processed

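The series holds 24 samples in 18 groups from CD-1 mice, per the labels. Forebrain was dissected at E12.5 and lens at P1. ChIP-seq libraries covered Pax6, RNA polymerase II, H3K4me1, H3K4me3, H3K27ac and H3K27me3 in both tissues, FAIRE was run in lens, and RNA-seq was run on forebrain, lens epithelium and lens fibers. Per the labels' protocols, chromatin was crosslinked, sonicated and precipitated with antibody, and RNA libraries were made from total RNA with a strand-specific dUTP method. All groups held 1 library except forebrain Pax6 (2, both tied to 1 peak list by the labels), forebrain input (4) and lens input (3). The inputs entered only through the authors' peak calls and the control reads per island, and no file of their own was used here.

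Peaks of Pax6, H3K4me3, H3K27ac and RNA polymerase II were called by the authors with MACS2 on the mouse build mm9, per the submitters' processing notes, which give no version, threshold, aligner or input library. The deposited lists give for each peak a fold enrichment at the summit over the control, a -log10 q-value and a summit offset. The largest q-values in the MACS2 lists lay between 0.00413 and 0.00966. How the authors combined the 2 forebrain Pax6 replicates is not given in the sources used here, so no value per replicate could be had. Islands of H3K4me1 and H3K27me3 were called by the authors with SICER on mm9, per the submitters' processing notes, with windows of 200 bp, gaps of 600 bp and an FDR of 0.001 per the labels in the names of the lists. The deposited island tables hold raw counts of ChIP and control reads per island, the ratio of ChIP over control scaled by library size, and the FDR of each island. The FAIRE list gives the start and end of each region as deposited by the authors and no score, so stricter or shorter versions of it could not be made. MACS2 and mm9 are named for it in the submitters' processing notes. RNA values are RPKM as deposited by the authors. TopHat2 (version 2), Cufflinks (version 2) and Cuffdiff are named in the submitters' processing notes with mm9 and without their roles, and the annotation, the counting of reads with several matches and any scaling between libraries are not given in the sources used here.

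The tests, gene lists, alternatives and the rule for named items were fixed before the data were examined, except those said to have been added later. The quartiles of peak strength, summit distances, X chromosome counts, combinations of marks, bootstrap intervals and crystallin shares were added afterwards. Intervals were overlapped at a minimum of 1 bp with code that gave the same counts as bedtools 2.31.1 in 12 of 12 settings tested on the lists, and recovered 300 of 300 overlaps planted between the Pax6 lists. Shares have exact Clopper-Pearson 95% intervals. Reads are not independent molecules and peaks are not replicates, so these intervals and all bootstrap intervals (2000 draws over peaks) cover counting error within the lists only. Chance overlap was described by 1000 circular shifts of a list within each chromosome, which keep the spacing of its intervals but ignore gaps and unmappable stretches of the assembly. Fold enrichment was used only to rank or describe peaks within a list. The coordinates printed are 1-based on mm9.

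For RNA, each pair of libraries was compared by log2((RPKM + 1)/(RPKM + 1)) over genes with at least 1 RPKM in either library, and genes with an absolute log2 ratio of at least 2 (4-fold) were counted. No p-value was computed, since each group held 1 library. Of 23947 symbols, 23812 had a current symbol or synonym in the RefSeq table of GRCm38.p6, which was used for names and gene types only, and 20436 were protein coding. The 25 gene lists held 317 genes, of which 313 were used (Ahsp, Hbb-b2, Pkm2 and Silv were not analysed here). They covered alpha and beta crystallins, gamma crystallins, fiber structure, lens epithelium, lens transcription factors, forebrain patterning, neural progenitors, postmitotic neurons, the cell cycle, cyclin-dependent kinase inhibitors, FGF response, the Notch pathway, basement membrane, glycolysis, autophagy and mitophagy, heat shock, housekeeping and genes reported as Pax6 targets. The lists for other cell types covered blood, endothelium, myeloid cells, retina and photoreceptors, pigment cells and ciliary epithelium, cornea and surface epithelium, and mesenchyme. For each list, members past a log2 ratio of 1 (2-fold) were counted, and its median was placed among 10000 random lists of the same size drawn within 100 ranks of each member's mean expression, as a description of these libraries. The procedure was run on simulated data, the fiber against epithelium ratios shuffled over 12090 genes. There 6% of unchanged random lists of 15 genes lay outside the central 95%, and 85.5% of lists shifted by a log2 ratio of 1 did. Shuffling removes any link of ratio to expression and random lists hold no jointly regulated genes. These rates therefore do not give the error rate of the real lists.

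Genes were named by this rule: in each comparison the 10 highest and the 10 lowest log2 ratios among genes with at least 10 RPKM in either library, Pax6 in every library, and the 4 members of each list with the largest absolute log2 ratio. For peaks, the 5 with the highest fold enrichment in each Pax6 list and the 5 shared pairs with the highest smaller value were taken, and the text gives those that stand for the rest. Gapdh and Pgam1 were named after their values were seen, and some genes that the rule names are not reported here. A gene listed at 0 in a library is given with its values and no fold, since 7348, 6582 and 9014 genes were listed at 0 in forebrain, epithelium and fibers and a 0 can be a failed estimate. Such genes still enter the counts and medians of lists at the value listed.

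Whole reads could not be recovered from the RPKM values. Over 642 genes below 0.1 RPKM, the ratio of forebrain to epithelium values had its most frequent value at a log2 of 0.6 (97 genes, 58 in the next bin), while ratios against the fiber library had no clear step (16 of 345 and 23 of 435 genes in the fullest bin), so relative depth was not set. The share of RPKM taken by crystallins in fibers is not a share of reads, and the summed RPKM of other coding genes was no lower there (in units of 1000 RPKM, 306.4 in fibers, 261.95 in forebrain and 217.5 in epithelium). How many reads other genes had in fibers was therefore not known. Very short transcripts are inflated in RPKM, and gene copies with near-identical sequence (gamma crystallins, histones, globins) are uncertain one by one.

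The alternatives were an overlap of 0.5 of the shorter interval, gaps of up to 1 kb, stricter thresholds (a q-value of 1e-05 for MACS2 and an FDR of 1e-10 for SICER), lists held to the same number of strongest intervals, pseudocounts of 0.1 and 5 RPKM, no filter and a filter of 5 RPKM, centring on the median of genes present in both libraries, rescaling after leaving out the 50 most abundant genes of each library, and a log2 threshold of 1. Added after the data were seen were counts of protein-coding genes only, Pax6 lists without peaks in islands with over 10 times the median control reads per kb, and forebrain H3K27me3 islands limited to the length covered by lens islands. Pax6 peaks near genes and the Pax6 motif at summits were planned and not analysed here, because no gene annotation or sequence of mm9 was used. Analysis was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.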

Results

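Chromatin and RNA of 2 mouse tissues that depend on the paired-domain and homeodomain transcription factor Pax6 were profiled, the embryonic forebrain at E12.5 and the newborn lens at P1. In both tissues ChIP-seq covered Pax6, RNA polymerase II and 4 histone modifications: H3K4me1, found at enhancers, H3K4me3, found at active promoters, H3K27ac, found at active enhancers and promoters, and H3K27me3, deposited by Polycomb complexes at silenced genes. FAIRE, which isolates nucleosome-poor open chromatin, was run in lens. RNA-seq was run on forebrain, on the lens epithelium, the proliferating cell layer at the front of the lens, and on the lens fibers, the elongated cells that fill the lens with crystallins. Each group held 1 library, except forebrain Pax6 (2 replicates, given as 1 peak list), forebrain input (4) and lens input (3). With 1 list or value per group there were no replicate values, so intervals cover counting error within a list only, and no difference below was checked against biological replicates. All lens samples were taken at P1 and all forebrain samples at E12.5, so tissue and age cannot be told apart in any comparison between them. The Pax6 lists held 3815 peaks in lens (median width 286 bp) and 3536 in forebrain (253 bp). The depth of the libraries behind the peak lists and RPKM values is not given in the sources used here. Islands of H3K4me1 held 1.26 M ChIP reads in lens and 5.11 M in forebrain, over 74.1 and 145.6 Mb, and those of H3K27me3 held 3.42 and 9.40 M, over 123.6 and 185.1 Mb.

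To ask how far Pax6 occupies the same sites in both tissues, the Pax6 lists were overlapped. Of the lens peaks, 1242 (32.6%, exact 95% interval 31.1% to 34.1%) overlapped a forebrain peak, and 1243 forebrain peaks (35.2%, 33.6% to 36.8%) overlapped a lens peak. Circular shifts of the list within chromosomes gave a mean of 3.17 and a maximum of 10 overlapping lens peaks. Within the overlapping pairs the summits lay a median of 24 bp apart, and 78.2% lay within 50 bp. The remaining 2573 lens peaks and 2293 forebrain peaks are called lens-only and forebrain-only here, which says that no peak was listed in the other tissue, not that Pax6 was absent there.

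The strongest Pax6 peak of the lens list, on chromosome 6 at 38710196 to 38710701 (mm9, as all coordinates here), had a fold enrichment of 54.2 in the authors' peak list and overlapped a forebrain Pax6 peak, H3K4me1 of both tissues, lens H3K27ac and lens FAIRE. The next, on chromosome 11 at 36626346 to 36626871, had a fold enrichment of 48.6 and overlapped a forebrain Pax6 peak and no other list. A peak on chromosome 8 at 6132090 to 6132780 (fold enrichment 44.7) was lens-only and overlapped H3K4me1 of both tissues, lens H3K27ac and lens FAIRE. A peak on chromosome 17 at 82598413 to 82599064 (44.6) was also lens-only and overlapped lens H3K4me1 and lens FAIRE. In forebrain, the strongest peak lay on chromosome 3 at 159514389 to 159515405, with a fold enrichment of 53.6. It overlapped a lens Pax6 peak, H3K4me1 of both tissues, forebrain H3K27me3 and lens FAIRE. All 5 strongest forebrain peaks overlapped a lens Pax6 peak, as did 3 of the 5 strongest lens peaks. The shared pair with the highest smaller fold enrichment lay on chromosome 4 at 141097567 to 141098433 in lens (37.8) and at 141097578 to 141098338 in forebrain (41.0). There it overlapped H3K4me1 of both tissues, forebrain H3K27ac and lens FAIRE. Genes near these positions were not analysed here.

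Shared Pax6 peaks were stronger than tissue-only peaks within each list, by the authors' fold enrichment. In lens the median was 7.89 at shared and 6.57 at lens-only peaks, a ratio of 1.2 (bootstrap 95% interval over peaks 1.15 to 1.25). In forebrain it was 8.30 against 6.32, a ratio of 1.31 (1.25 to 1.37). From the weakest to the strongest quartile of fold enrichment, the share of peaks found in the other tissue went from 22.2% to 47.7% in lens and from 17.2% to 60.3% in forebrain. The strongest quartile of lens peaks also overlapped lens H3K4me1 (56.6% against 33.0%), H3K27ac (19.7% against 8.07%) and FAIRE (52.3% against 32.7%) more often than the weakest, with exact 95% intervals that did not overlap. H3K4me3 lay at 9.01% of the weakest and 4.61% of the strongest lens quartile, but 55 of the 57 lens peaks in islands rich in control reads overlapped it. Without those 57 the shares were 3.62% (2.52% to 5.02%) and 4.47% (3.24% to 5.99%), so that order came from these peaks, while the intervals for H3K4me1, H3K27ac and FAIRE still did not overlap. Forebrain peaks did not have this order for the forebrain marks, with H3K4me1 at 69.7% of the weakest and 62.9% of the strongest quartile and H3K27ac at 21.9% and 19.0%, while lens FAIRE lay at 28.8% and 38.2%.

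**Figure D1:**
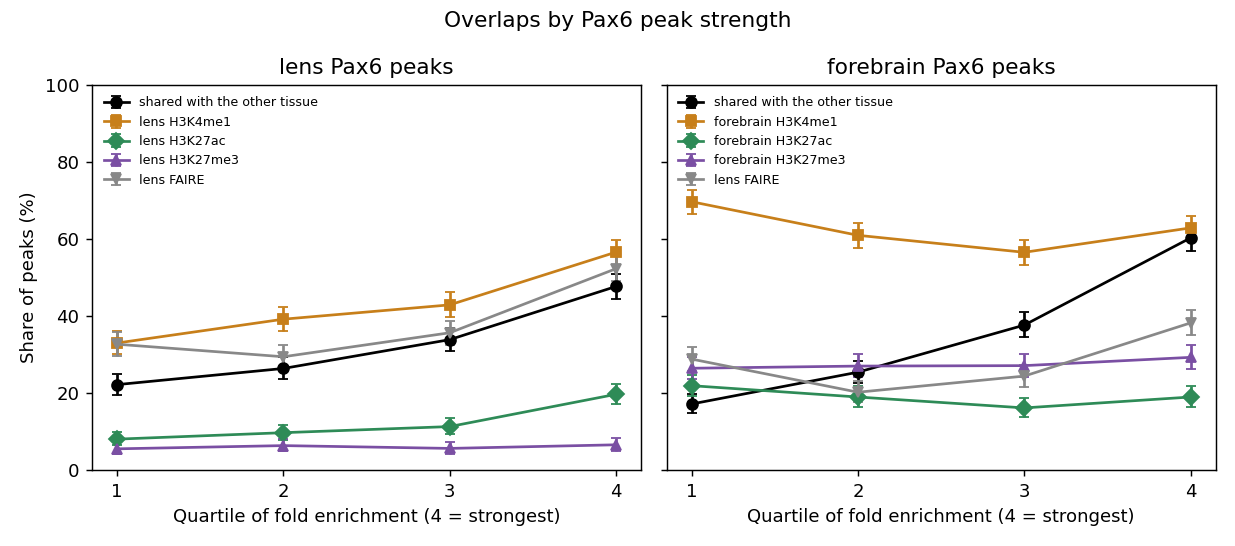
Share of Pax6 peaks (%, y axis) that overlap each other list, by quartile of the authors' fold enrichment (x axis, 4 is strongest), for lens peaks on the left and forebrain peaks on the right; bars are exact 95% intervals. The share found in the other tissue is 22.2% in the weakest and 47.7% in the strongest lens quartile, and 17.2% and 60.3% in forebrain.

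The marks at Pax6 peaks describe the chromatin that Pax6 occupies in each tissue. In lens, 42.9% of Pax6 peaks (41.4% to 44.5%) lay in H3K4me1 islands, 12.2% (11.2% to 13.3%) overlapped H3K27ac and 37.5% (36.0% to 39.1%) overlapped open chromatin by FAIRE, against 3.32%, 0.719% and 2.88% in shifted lists. In forebrain, H3K4me1 was present at 62.5% (60.9% to 64.1%) and H3K27ac at 19.0% (17.8% to 20.4%) of Pax6 peaks, against 6.42% and 1.08% in shifted lists. Promoter-type H3K4me3 lay at 5.74% of lens and 5.46% of forebrain peaks, and RNA polymerase II at 1.10% and 1.02%. Of the 219 lens peaks with H3K4me3, 55 lay in islands rich in control reads, against 0 in forebrain, so the lens share is inflated by these peaks. The repressive mark H3K27me3 covered 27.5% (26.0% to 29.0%) of forebrain Pax6 peaks, against 6.91% in shifted lists. For lens peaks it covered 6.06% (5.32% to 6.86%), against a mean of 4.54% and a maximum of 5.74% in shifted lists. Of the forebrain Pax6 peaks in H3K4me1 islands, 31.8% (29.9% to 33.8%) also lay in H3K27me3 islands, against 20.3% (18.2% to 22.6%) of those outside H3K4me1. Peaks with forebrain H3K27ac lay in H3K27me3 in 19.8% of cases (16.8% to 23.0%), and peaks without it in 29.3% (27.6% to 31.0%). None of the 4 histone marks was listed at 1907 of the 3815 lens peaks and 945 of the 3536 forebrain peaks (26.7%).

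These shares depended on the lists. With lists of equal length, forebrain H3K4me1 fell on 32.9% of forebrain Pax6 peaks, and H3K27ac reached 23.3% of lens and 29.4% of forebrain peaks with 1 kb gaps allowed and 5.40% of lens peaks with overlap of at least 0.5 of the shorter interval.

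To ask whether tissue-only binding went with tissue-only marks, the marks of both tissues were compared at the same peaks. Lens-only Pax6 peaks lay in lens H3K4me1 more often (43.9%) than in forebrain H3K4me1 (26.3%), a difference of 17.6 percentage points (bootstrap 95% interval 15.6 to 19.7). Forebrain-only peaks lay in forebrain H3K4me1 in 70.1% and in lens H3K4me1 in 36.2% of cases, a difference of 33.9 points (31.8 to 36.2). Set against shifted lists, these shares were 10.9 times in forebrain and 11.1 times in lens, so this difference did not hold relative to the background of each list. For lens-only peaks the H3K4me1 shares were 13.4 times in lens and 4.09 times in forebrain. H3K27ac of the bound tissue exceeded that of the other tissue by 4.0 points (2.84 to 5.21) at lens-only and by 12.6 points (11.1 to 14.2) at forebrain-only peaks. At shared peaks, H3K4me1 was listed at 40.9% in lens and 48.6% in forebrain, and H3K27ac at 15.1% and 18.2%. Forebrain-only peaks lay in forebrain H3K27me3 islands in 31.5% and in lens H3K27me3 islands in 16.3% of cases, a difference of 15.2 points (13.3 to 17.1). Lens-only peaks also lay in forebrain H3K27me3 islands more often (10.3%) than in lens islands (4.94%), a lens minus forebrain difference of -5.40 points (-6.57 to -4.28), and shared peaks did so in 20.1% and 8.37% of cases. Relative to shifted lists, the forebrain and lens H3K27me3 shares were 4.65 and 3.69 times at forebrain-only peaks. They were 1.52 and 1.11 times at lens-only and 2.85 and 1.79 times at shared peaks. The point differences thus partly reflect the larger background of the forebrain list. The lens share of 4.94% at lens-only peaks lay within the range of shifted lists (maximum 6.34%). Lens FAIRE regions overlapped 37.6% of lens-only, 37.4% of shared and 22.8% of forebrain-only peaks.

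With both lists of each pair held to the same number of strongest intervals, the H3K4me1 difference at forebrain-only peaks was lost. It was -0.255 points (35.8% against 36.1%), while the difference at lens-only peaks became 31.2 points. With stricter thresholds the H3K4me1 differences were 9.13 points at lens-only and 38.2 points at forebrain-only peaks. The H3K27ac difference at lens-only peaks was 6.29 points with equal lists, 11.1 points with 1 kb gaps and 0.0775 points when an overlap of 0.5 of the shorter interval was required.

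**Figure D2:**
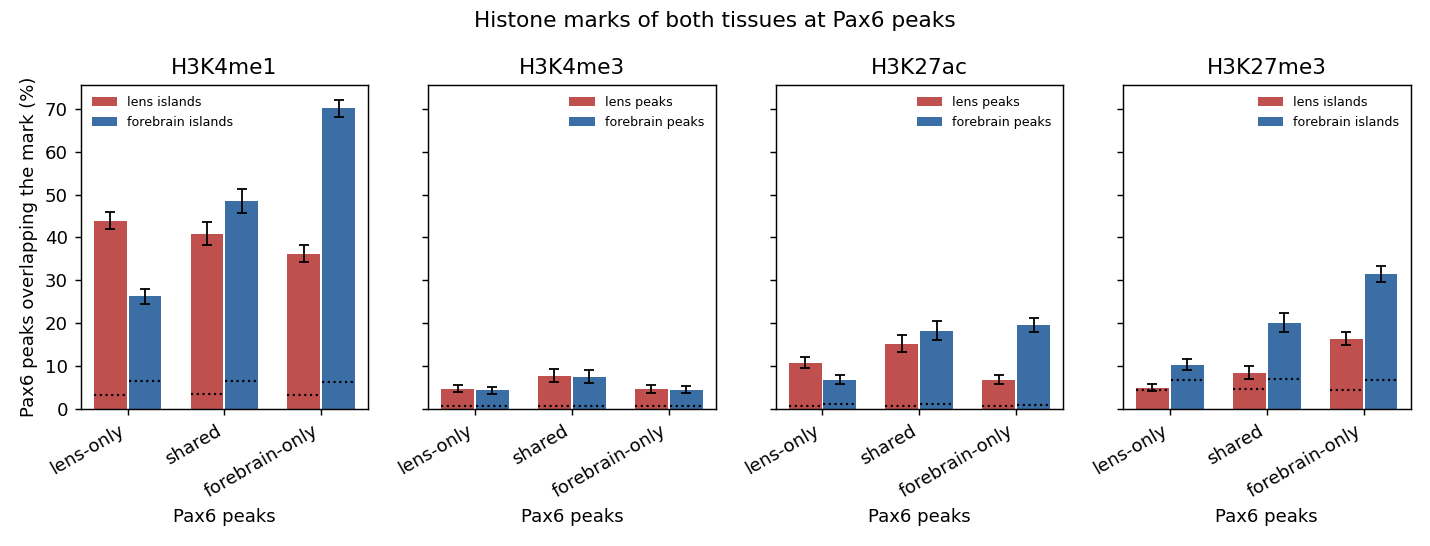
Share of lens-only (n = 2573), shared (n = 1242) and forebrain-only (n = 2293) Pax6 peaks (%, y axis) that overlap each histone mark in lens (red) and forebrain (blue); bars are exact 95% intervals and dotted lines the mean of shifted lists. H3K4me1 is listed at 43.9% of lens-only peaks in lens against 26.3% in forebrain, and at 70.1% of forebrain-only peaks in forebrain against 36.2% in lens. The H3K4me1 means of shifted lists at forebrain-only peaks are 6.40% in forebrain and 3.27% in lens.

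Across the genome, H3K4me3 was the most alike between the tissues of the 5 lists compared, in both directions. Of the lens H3K4me3 peaks, 86.7% (86.2% to 87.2%) overlapped a forebrain H3K4me3 peak, and 92.1% of forebrain peaks overlapped a lens peak. The corresponding shares were 68.1% and 46.4% for H3K27ac, 66.2% and 33.0% for H3K4me1, 61.6% and 56.4% for H3K27me3, and 35.8% and 69.6% for RNA polymerase II. The list with more intervals had the lower share for H3K4me1 (40774 forebrain against 20811 lens islands) and polymerase (1704 forebrain against 3332 lens peaks), and for H3K4me3 and H3K27ac. For H3K27me3 the lens list had more islands (31034 against 25473) and the higher share. With equal lists the lens share for H3K4me1 was 41.1%.

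Bivalent regions, in which the promoter mark H3K4me3 lies within Polycomb-marked H3K27me3, are known from developmental genes that are kept silent. In forebrain, 24.9% (24.2% to 25.6%) of the 15407 H3K4me3 peaks overlapped an H3K27me3 island, against 7.86% in shifted lists. In lens it was 15.4% (14.9% to 16.0%) of 16289 peaks, against 5.53%. With 1 kb gaps the shares were 35.3% in forebrain and 24.7% in lens, and when an overlap of 0.5 of the shorter interval was required 18.5% and 9.99%, so the order of the tissues held; forebrain H3K27me3 islands were longer than lens islands (median 5000 bp against 3000 bp).

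The X chromosome carried 22.8% (22.3% to 23.3%) of the lens H3K27me3 islands and 15.04% (14.6% to 15.5%) of the forebrain ones. It carried 0.264% of lens and 0.834% of forebrain H3K4me1 islands, and 1.52% and 1.44% of lens and forebrain Pax6 peaks.

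Open chromatin in lens comprised 107737 FAIRE regions over 38.9 Mb. Few of these regions overlapped any single lens ChIP list, with H3K4me1 the highest at 5.50% (5.37% to 5.64%). The other shares were 2.45% for H3K27me3, 2.39% for H3K4me3, 2.31% for H3K27ac, 1.29% for Pax6 and 0.601% for RNA polymerase II. Forebrain lists overlapped lens FAIRE regions at higher shares for H3K4me1 (9.68%), H3K27me3 (5.05%) and H3K27ac (2.93%). Their shares were lower for H3K4me3 (2.25%), Pax6 (0.904%) and RNA polymerase II (0.320%). Seen from the lens ChIP lists, FAIRE regions lay at 37.5% of Pax6 peaks, 19.7% of polymerase peaks, 16.9% of H3K4me3 peaks and 13.6% of H3K27ac peaks. These were 13.0, 6.48, 3.37 and 3.46 times the shifted lists. Of the broader H3K4me1 islands 25.3% overlapped a FAIRE region, 1.70 times the shifted lists. At H3K27me3 islands FAIRE was depleted, with 7.51% of islands overlapping a region, 0.551 times the shifted lists. For the forebrain lists, lens FAIRE lay at 10.2 (Pax6), 6.38 (polymerase), 3.41 (H3K4me3) and 2.77 (H3K27ac) times the shifted lists. For forebrain H3K4me1 and H3K27me3 islands it was 1.496 and 0.785 times. These ratios therefore do not tie open chromatin in lens to the marks of lens alone. With stricter island thresholds 3.33% of FAIRE regions overlapped lens H3K4me1.

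Expression was given as RPKM per gene for 23947 symbols in 3 libraries. Pax6 itself was listed at 28.1 RPKM in forebrain, 141.6 in lens epithelium and 24.0 in lens fibers, a log2 ratio of 2.29 for epithelium over forebrain and of -2.51 for fiber over epithelium. The 16 crystallins examined made up 0.0411% of the summed RPKM of protein-coding genes in forebrain, 9.07% in epithelium and 85.5% in fibers. All ratios are log2((RPKM + 1)/(RPKM + 1)), which understates the difference of genes with low values. Genes present in both libraries of a pair had a median ratio of -0.05 for epithelium over forebrain, -0.19 for fiber over forebrain and -0.20 for fiber over epithelium, and directions below are relative to shifts of this size.

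Lens epithelium at P1 was compared with forebrain at E12.5, and the differences below mix tissue with age. Of 12619 genes, 591 were at least 4-fold higher and 410 at least 4-fold lower in epithelium. Among the highest ratios were those of Cryaa, the small heat shock protein alpha A crystallin (11819.8 RPKM against 18.2, log2 ratio 9.27), and the retinaldehyde dehydrogenase gene Aldh1a1 (784.4 against 0.378, 9.15). All 8 alpha and beta crystallins and all 8 gamma crystallins were at least 2-fold higher, with list medians of 7.54 and 4.44. Per 100000 RPKM in fibers, epithelium held 84.7 RPKM of Cryga, 81.9 of Crygb, 110.3 of Cryge and 83.2 of Crygf. Crygc and Crygd were at 350.6 and 137.0 on this scale. Whether the gamma crystallin transcripts of this library came from epithelial cells or from fibers was not tested. Lens epithelium markers were higher for 12 of 12 genes, among them the cell adhesion gene Cdh1 (62.3 against 0.0821 RPKM, 5.87), Clu (5.69) and Trpm3 (4.73). Basement membrane genes were higher for 15 of 16, led by the type IV collagen gene Col4a2 (532.4 against 10.8 RPKM, 5.50) and Nid1 (5.39), which belong to the set of genes that build the lens capsule. Fiber structure genes were higher for 10 of 11, including Lim2 (7.11) and Gja3 (6.57). The lens transcription factors were higher for 15 of 18 (median 1.98), with Mab21l2 at 4.35 and Prox1 at 4.15, and Pitx3 and Foxe3 at 35.0 and 19.4 RPKM and listed at 0 in forebrain.

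Forebrain patterning genes were lower in epithelium for 25 of 26 genes, with a median of -2.83. For 6 of these 26 the epithelium value was listed at 0. Among them were Emx1, a homeobox gene of the dorsal telencephalon (0.0496 against 76.0 RPKM, -6.20), the proneural gene Neurog2 (-4.96) and Eomes (-4.24). Postmitotic neuron genes were lower for 18 of 19 (median -3.56), led by the neuronal tubulin Tubb3 (6.23 against 460.6 RPKM, -6.00) and Neurod6 (-5.23). Neural progenitor genes were lower for 10 of 15, with Fabp7 at -6.29 and Sox3 at -2.71, and higher for 2, one of which was Pax6. Cell cycle genes were at least 2-fold lower for 20 of 22 (median -1.41), including Cdc20 (-2.15) and Top2a (-1.79). Each of these 4 medians lay below all 10000 random lists matched on expression, and the medians of both crystallin lists, fiber structure, lens epithelium, lens transcription factors and basement membrane lay above all of them.

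Markers of other cell types also differed between these libraries. Endothelial markers had a median of 1.04 (above 99.95% of random lists), with 6 of 10 genes higher in epithelium, including Tek (12.8 against 2.46 RPKM) and Egfl7 (65.4 against 17.6, 1.84). Pigment cell and ciliary markers were higher for 6 of 6 genes (median 2.94), with Pmel at 52.7 against 0.0916 RPKM (5.62) and Tyrp1 at 21.2 against 0.0196 (4.44). In the retina list Rax (15.8 against 0.188 RPKM, 3.82) was higher, Isl1 (-3.12) and Otx2 (-1.92) were lower, and the list median of 0.83 was inside the central range. Myeloid markers had a median of 0.67, also inside it, with Lyz2 at 2.13. Blood genes were lower for 6 of 8 (median -2.74), led by the embryonic globin Hbb-y, at 4223 RPKM in forebrain and 1.995 in epithelium (-10.46), and mesenchyme genes for 5 of 9 (-1.17), with Lum at -3.98 and Col3a1 at -3.95. The globin gene Hbb-b1 was at 153.2 RPKM in forebrain and 172.8 in epithelium (0.17). As the ages differ too, the blood median does not measure the blood content of the samples. The gene counts varied with the pseudocount, from 1112 higher and 865 lower at 0.1 RPKM to 259 and 137 at 5 RPKM.

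Lens fibers differed from forebrain in more genes: of 12205, 777 were at least 4-fold higher and 1387 at least 4-fold lower. The 10 highest ratios all belonged to crystallins, from Cryba2 (86595.8 against 2.18 RPKM, 14.74) and Crybb1 (109869 against 3.08, 14.72) to Crygc (13.52). Fiber structure genes were higher for 14 of 14 (median 8.91), including Lim2 (16275.5 RPKM, 12.94), which encodes a fiber membrane protein, and the beaded filament genes Bfsp2 (6941 RPKM, 11.82) and Bfsp1 (11.64). Lens transcription factors were higher for 7 of 13 and lower for 3, with Hsf4 at 7.23, Maf at 5.95 and Prox1 at 5.92, and Pitx3 at 37.3 RPKM and listed at 0 in forebrain. Basement membrane genes were higher for 12 of 16 (median 2.54), led by Col4a2 and Nid1 (both 5.32). Lens epithelium markers were higher for 6 of 11 and lower for 1, with Dkk3 at 7.24 and Gja1, which encodes connexin 43, at -3.59.

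Cell cycle genes were lower in fibers for 22 of 22 (median -4.32), among them Top2a (0.616 against 140.2 RPKM, -6.45), Cdk1 (-5.43) and Ccna2 (-5.38). The lowest ratios were those of Hbb-y (-11.67) and of histone genes such as Hist1h2af (1.25 against 1313 RPKM, -9.19) and Hist1h4k (5.14 against 2429, -8.63), whose near-identical copies share reads and are uncertain one by one. Forebrain patterning genes were lower for 26 of 26 (median -3.22), neuron genes for 18 of 19 (-3.52) and progenitor genes for 12 of 15 (-2.77), with Tubb3 at -6.52, Neurog2 at -5.33 and Hes5 at -5.65. The lower counts and medians include genes listed at 0 in fibers: 15 of the 26 patterning, 8 of the 19 neuron and 2 of the 15 progenitor genes. Notch pathway genes were lower for 11 of 14 (median -1.97), with Dll1 at -4.47, while the Notch ligand gene Jag1 was higher (81.8 against 5.19 RPKM, 3.74). Blood genes were lower for 8 of 8 (-6.63), mesenchyme genes for 8 of 9 (-1.89), endothelial markers for 7 of 9 (-2.20) and myeloid markers for 5 of 7 (-1.64), of which 2, 3, 4 and 2 genes tested were listed at 0 in fibers. Of these lists, the crystallins, fiber structure and basement membrane lay above all 10000 random lists, and cell cycle, patterning, neuron, progenitor and blood genes below all of them. Lens transcription factors lay at percentile 99.97, lens epithelium at 99.92, and the Notch, endothelial, myeloid and mesenchyme lists at 0.05, 0.11, 0.13 and 0.19. The endothelial list was inside the central range among genes of at least 5 RPKM (percentile 21.1), and the myeloid list was inside it with a pseudocount of 0.1 (percentile 38.2) and with no filter on low values (percentile 4.03). The number of lower genes was 2661 with a pseudocount of 0.1 and 404 with 5 RPKM, and that of higher genes 419 with 5 RPKM.

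Fibers were then compared with the epithelium from which they form. Of 12090 genes, 453 were at least 4-fold higher and 982 at least 4-fold lower in fibers. Gamma crystallins were higher for 8 of 8 (median 9.66), led by Crygb (188047 against 153.9 RPKM, 10.25) and Cryga (403509 against 341.9, 10.20), and alpha and beta crystallins for 8 of 8 (6.29), led by Cryba4 (8.52). Crygd, Cryge and Crygf are close in sequence and their separate values are uncertain. Fiber structure genes were higher for 13 of 14 (median 5.68), with Bfsp1 (5501 against 10.6 RPKM, 8.89), Birc7 (7.49) and Lctl (6.93). Among lens transcription factors 5 of 18 were higher and 9 lower (median -1.16): Hsf4, a heat shock factor of the fiber program, was at 156.5 against 1.34 RPKM (6.07), while Mab21l2 (-4.76), Foxe3 (0.433 against 19.4 RPKM, -3.83) and Meis1 (-2.82) were lower. Lens epithelium markers were lower for 8 of 13 and higher for 3, with Gja1 at 0.440 against 98.8 RPKM (-6.11), Cdh1 at -5.03 and Aqp1 at -4.99. Basement membrane genes were lower for 8 of 16 (median -1.07), with Col18a1 at -4.95 and Lamc1 at -2.57.

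Cell cycle genes were lower in fibers for 22 of 22 (median -2.97), led by Top2a (0.616 against 39.7 RPKM, -4.65), Cdk1 (-4.27) and Mcm6 (-4.20). Notch pathway genes were lower for 11 of 14 (-1.56), with Hes5 at -3.84, Hes1 at -3.35 and Notch2 at -3.32, and progenitor genes for 11 of 13 (-2.51), with Prom1 at -3.24. Markers of other cell types were lower in fibers beside these groups: endothelial markers for 9 of 10 genes (median -2.84; Cldn5 at 38.3 RPKM in epithelium and listed at 0 in fibers, with Egfl7 the exception at 32.6 RPKM in fibers), myeloid markers for 9 of 9 (-1.97; C1qa at -3.17), pigment and ciliary markers for 5 of 6 (-3.89; Pmel at -4.94) and blood genes for 4 of 4 (-3.59; Hbb-b1 at -5.64). Listed at 0 in fibers were 4 endothelial, 4 myeloid and 2 pigment genes. Gamma crystallins and fiber structure lay above all 10000 random lists, and cell cycle, progenitor, basement membrane, endothelial and pigment genes below all of them. The lens epithelium, transcription factor, blood, myeloid and Notch lists lay at percentiles 0.02, 0.03, 0.04, 0.05 and 0.08. The myeloid list was inside the central range among genes of at least 5 RPKM (percentile 8.65), and the blood list with no filter (9.35). Among single genes, the collagen gene Col9a1 had one of the lowest ratios (0.589 against 207.4 RPKM, -7.03). Several of the most extreme ratios belonged to small RNA genes, such as Mir8112 (636.6 RPKM in fibers, listed at 0 in epithelium), for which a short length inflates RPKM. The number of lower genes was 2191 with a pseudocount of 0.1 and 267 with 5 RPKM, and that of higher genes 271 with 5 RPKM.

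**Figure D3:**
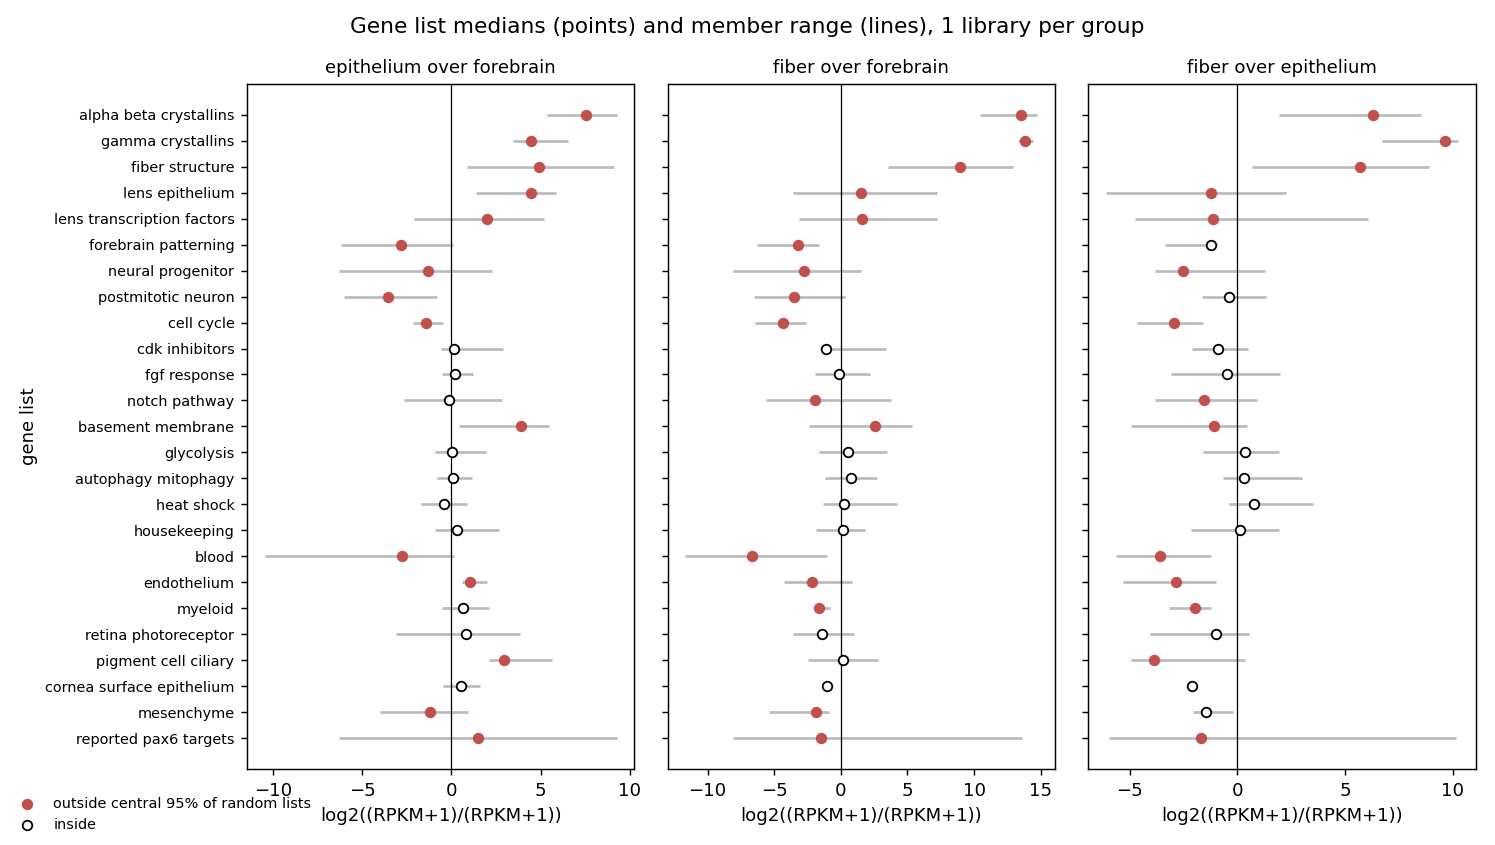
Median log2((RPKM + 1)/(RPKM + 1)) of each of 25 gene lists (points, x axis) with the range of its members (lines), for the 3 pairs of RNA libraries; filled points lie outside the central 95% of 10000 random lists matched on expression. Gamma crystallins have medians of 4.44, 13.78 and 9.66, and cell cycle genes of -1.41, -4.32 and -2.97, from left to right.

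Genes reported as Pax6 targets in lens or brain went both ways. In epithelium against forebrain 12 of 20 were higher and 7 lower (median 1.49, above all random lists), from Cryaa (9.27) and Optc (4.93) to Fabp7 (-6.29) and Neurog2 (-4.96). In fibers against forebrain 4 of 17 were higher and 10 lower (median -1.49, percentile 0.07), with Crygf at 13.62 and Maf at 5.95. The median of this comparison was inside the central range with no filter on low values (percentile 5.50). In fibers against epithelium 4 of 18 were higher and 13 lower (median -1.71, below all random lists), with Optc at -5.98 and Hes5 at -3.84. Pax6 itself is a member of this list.

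Several lists had medians inside the central range in all 3 comparisons. Cyclin-dependent kinase inhibitors had medians of 0.15, -1.09 and -0.92 for epithelium over forebrain, fiber over forebrain and fiber over epithelium, although Cdkn1c was at 38.8 RPKM in forebrain, 295.1 in epithelium and 411.6 in fibers. FGF response genes had medians of 0.21, -0.14 and -0.48, with Fgfr3 higher (2.16) and Dusp6 lower (-1.92) in fibers than in forebrain, and the second of these medians was outside among genes of at least 5 RPKM (1.25, percentile 99.6). Glycolysis genes had medians of 0.02, 0.54 and 0.35, with Aldoc at 3.44 and Ldha at -1.62 in fibers over forebrain. Autophagy and mitophagy genes had medians of 0.08, 0.73 and 0.30, with Gabarapl1 at 238.3 RPKM in fibers against 28.7 in epithelium (3.01), and the 0.73 was outside with pseudocounts of 0.1 and 5 RPKM (percentiles 98.4 and 98.0). Heat shock genes had medians of -0.41, 0.25 and 0.75, with Hspb1 at 24.1 RPKM in fibers and 1.19 in epithelium (3.52). Housekeeping genes had medians of 0.29, 0.13 and 0.10, with Gusb at 2.68 in epithelium over forebrain. Gapdh, at 0.483, 0.199 and 0.573 RPKM in forebrain, epithelium and fibers, was listed far below the level known for this gene, which has many processed pseudogenes. Eno1 (1.80, 0.781 and 3.09 RPKM), Pgam1 (6.45, 5.22 and 6.28) and Ppia (0.386, 1.53 and 3.40) were also listed low, and the glycolysis and housekeeping medians that include them carry the same doubt. Cornea and surface epithelium markers were tested for at most 2 genes, with medians of 0.56, -1.005 and -2.09. The retina median of 0.83 given above was outside with a pseudocount of 0.1 (percentile 98.6). Retina genes had medians of -1.41 and -1.004 in fibers against forebrain and epithelium, over 4 and 6 genes, inside the central range except after rescaling without the most abundant genes (0.64, fiber over forebrain) and among genes of at least 5 RPKM (0.43, fiber over epithelium). For pairs of libraries not given above, medians inside the central range were -0.15 for Notch pathway genes in epithelium over forebrain, 0.18 for 2 pigment cell genes in fiber over forebrain, and -1.24 for 5 patterning genes, -0.38 for 6 neuron genes and -1.46 for 5 mesenchyme genes in fiber over epithelium. Of these, the pigment list was outside with no filter (98.2), and the patterning list in fiber over epithelium with no filter (1.28) and with a pseudocount of 5 RPKM (1.67), as was the cornea list there with no filter (1.98).

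Crystallin transcripts were also listed in the forebrain library at low values, from 0.758 to 18.2 RPKM. Over the gamma crystallins Cryga to Crygf, forebrain held 4.40 to 7.17 RPKM per 100000 RPKM of the fiber library, and epithelium 81.9 to 350.6.

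**Figure D4:**
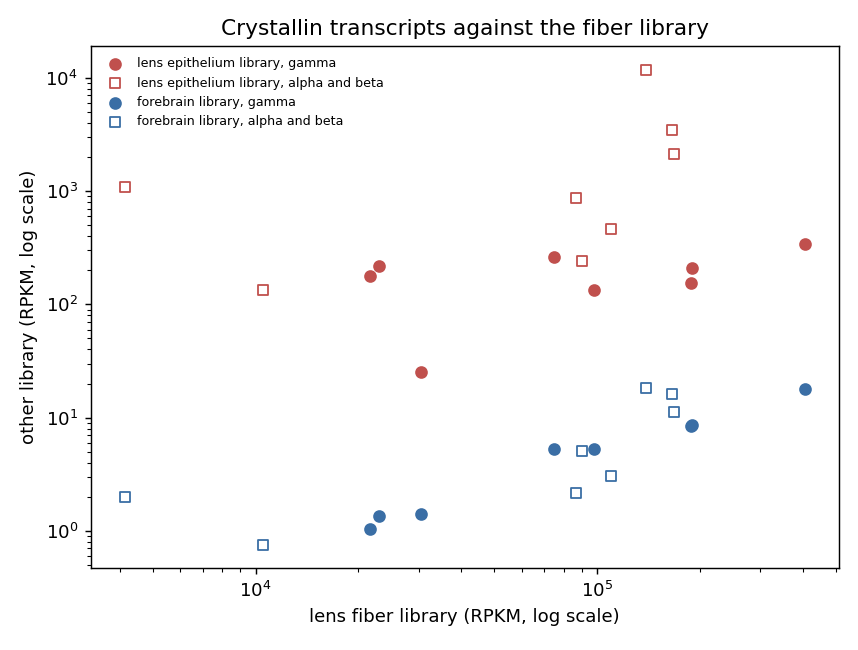
RPKM of each of the 16 crystallins in the epithelium (red) and forebrain (blue) libraries (y axis, log scale) against the fiber library (x axis, log scale), gamma crystallins as filled circles. The blue circles of Cryga to Crygf lie at 4.40 to 7.17 RPKM per 100000 RPKM in fibers.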

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

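The tests in this part were chosen only after the results were seen, except that of Pax6-free H3K4me1 islands, as were the limits for picking out results (list medians of opposite sign with both at least 0.5 in size and at least 5 members, single genes with both log2 ratios at least 2 in size). With 1 library per group, none of the differences between the lens libraries given here was tested.

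Both lens libraries were compared with forebrain, and 3 gene lists and 3 genes of the lists stood on opposite sides. Endothelial markers had a median log2 ratio of 1.04 in epithelium and -2.20 in fibers, myeloid markers of 0.67 and -1.64, and reported Pax6 targets of 1.49 and -1.49. Col18a1, which encodes a basement membrane collagen, was at 2.55 in epithelium and -2.39 in fibers. The pigment cell gene Dct was at 2.13 and -2.45, and the connexin gene Gja1 at 2.52 and -3.59.

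Markers of vessel, myeloid and pigment cells were present in the epithelium library, with Pmel at 52.7, Cldn5 at 38.3 and C1qa at 11.4 RPKM, and no member of these lists is in another list used here. Egfl7 stood apart from the other vessel markers, at 65.4 RPKM in epithelium and 32.6 in fibers, where the next highest was Tek at 1.14. All 3 lists lay below the 2.5th percentile of matched random lists in fiber over epithelium, the highest at 0.05. They thus fell further than genes of like mean expression. These percentiles are part of the pattern and were known when the test was written, so they do not decide between explanations. A general loss of scarce transcripts in the fiber library stays open. Cells of other types in the epithelium sample, such as vessels, resident myeloid cells and ciliary or pigment cells, are a candidate explanation without an independent test. Expression of these genes by the lens epithelium itself stays open, and no sorting step is given in the sources used here. Among genes of at least 5 RPKM the myeloid list lay at percentile 8.65, over 3 genes.

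Crystallin transcripts were listed in the forebrain library at up to 18.2 RPKM. Over 16 crystallins the SD of the log2 ratio of forebrain to fiber values was 0.986, against 2.43 for epithelium to fiber, so the forebrain values followed the fiber profile, as a small carry-over of reads or RNA from the fiber library would give. Carry-over from the epithelium library as the only source is argued against by the larger SD of forebrain to epithelium values, 1.81. The SDs cannot speak to a mix of both lens libraries. Per 100000 RPKM in fibers, Cryab, Cryaa and Crybb3 were highest in forebrain (48.5, 13.1 and 9.75) and also in epithelium (26476.5, 8508 and 2086). A part from epithelium thus stays open. Embryonic eye tissue in the forebrain sample cannot be told apart from carry-over: the highest of 5 eye markers was at 0.188 RPKM in forebrain, and what a small share of embryonic eye would give was not measured. Low expression of crystallins in embryonic forebrain stays open and untested, and Cryab, at 48.5 RPKM per 100000 in fibers, lay farthest above the others.

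Forebrain Pax6 peaks lay in H3K27me3 islands more often (27.5%) than lens Pax6 peaks did in theirs (6.06%), and the forebrain islands were longer and held more reads. In the lens islands alone, forebrain-only peaks were marked more often than lens-only peaks by 11.4 percentage points (9.62 to 13.1), which argues against depth and island length as the whole cause, although limiting forebrain islands to the length covered by lens islands lowered the share to 21.2%. The centres of 38670 forebrain H3K4me1 islands without Pax6 overlapped H3K27me3 in 18.5% (18.1% to 18.9%), below the 31.8% (29.9% to 33.8%) of Pax6 peaks in H3K4me1. This argues against a general property of these islands as the whole cause. It does not exclude a part, as 18.5% lay above the 6.91% of shifted forebrain Pax6 lists. The centres were not matched to Pax6 peaks on island length or strength. A mixture of cells in forebrain, with H3K4me1 and Pax6 in some and H3K27me3 in others, and a difference of tissue or age both stay open and were not tested.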

How the results depend on the processing

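Choices added only after the results were seen were the protein-coding count, the Pax6 lists without control-rich islands and the H3K27me3 length limit. Of 194 recomputed values of the comparisons, 116 stayed within the interval or 1.5-fold limit of the reported value. Of the rest, 77 moved beyond it and 1 changed sign, to a difference of -0.255 points. Of 775 values of lists, single genes and further overlaps, 648 stayed and 111 moved. A further 16 list medians crossed the edge of the central 95% of random lists (6 inward, 10 outward). Some values that stayed could not move and say nothing on stability. They include 141 of the 648 and the list counts under centring, which shifts every gene of a pair alike, gene counts with no filter, values from lists that equal numbers left whole, and forebrain Pax6 shares after 1 peak was left out. The cause of a move was not tested unless stated. Gaps can only raise an overlap share, and a larger required overlap can only lower it, by construction.

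With equal numbers of strongest intervals, 20811 of the 40774 forebrain H3K4me1 islands were used. The forebrain minus lens H3K4me1 difference at forebrain-only Pax6 peaks was then lost (-0.255 points). The lens-only H3K4me1, H3K27ac and H3K27me3 differences were 31.2, 6.29 and -6.76 points, and the forebrain-only H3K27ac and H3K27me3 differences 9.18 and 17.3. Lens peaks had H3K27me3 in 4.75%, forebrain peaks H3K4me1 in 32.9% and H3K27ac in 15.9%, and 33.5% of forebrain Pax6 peaks were shared. Shared lens shares were 41.1% (H3K4me1), 89.2% (H3K4me3), 62.0% (H3K27ac), 66.4% (H3K27me3) and 50.7% (polymerase), and lens H3K4me3 in H3K27me3 13.3%.

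With 1 kb gaps, lens Pax6 peaks had H3K4me1 in 45.3%, H3K27ac in 23.3%, H3K27me3 in 8.81% and FAIRE in 44.3%, forebrain peaks H3K4me1 in 66.1%, H3K27ac in 29.4% and H3K27me3 in 37.0%. The H3K27ac differences were 11.1 (lens-only) and 16.7 points (forebrain-only), that of H3K27me3 22.3. Shared lens shares were 68.0%, 91.4%, 76.0%, 63.7% and 37.9% in the same order, H3K4me3 in H3K27me3 24.7% (lens) and 35.3% (forebrain), and FAIRE in H3K4me1 7.30%.

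With an overlap of 0.5, H3K27ac lay at 5.40% of lens and 12.9% of forebrain Pax6 peaks and FAIRE at 35.2% of lens peaks. The H3K27ac differences were 0.0775 (lens-only) and 9.91 points (forebrain-only). Shared lens shares were 63.8%, 86.0%, 66.2% and 59.4% for the histone marks in the same order, H3K4me3 in H3K27me3 9.99% (lens) and 18.5% (forebrain), and FAIRE in H3K4me1 5.17%.

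With stricter thresholds, H3K4me1, H3K27ac and H3K27me3 lay at 31.7%, 11.1% and 4.53% of lens peaks, and H3K4me1 and H3K27ac at 55.3% and 17.4% of forebrain peaks. The H3K4me1 differences were 9.13 (lens-only) and 38.2 points (forebrain-only), that of H3K27me3 at forebrain-only peaks 17.2. Shared lens shares were 67.3%, 88.4%, 71.5% and 68.4% for the histone marks, H3K4me3 in H3K27me3 12.3% (lens) and 22.9% (forebrain), and FAIRE in H3K4me1 3.33%. Forebrain H3K27me3 islands limited to the lens length covered 21.2% of forebrain Pax6 peaks. Leaving out 57 lens and 1 forebrain Pax6 peaks in control-rich islands moved 1 of 14 values, the share of lens peaks with lens H3K4me3, which fell since 55 of the 57 overlapped it.

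For epithelium over forebrain, higher and lower genes were 1112 and 865 at a pseudocount of 0.1, 259 and 137 at 5, and 1731 and 1503 at a log2 threshold of 1. For fiber over forebrain they were 2661 lower at 0.1, 419 and 404 at 5, and 1942 and 3860 at the threshold of 1; for fiber over epithelium 2191 lower at 0.1, 271 and 267 at 5, and 1374 and 3419. These follow from the scale and the threshold. The 5 RPKM filter, centring, rescaling and protein-coding genes only moved no count by over 1.5 times; with no filter none can move, as 4-fold at a pseudocount of 1 needs 3 RPKM. The share of higher genes among those counted, 59.0%, 35.9% and 31.6% in the same order, was 61.4%, 44.9% and 40.9% after centring and 62.5%, 30.1% and 22.5% after rescaling.

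Depth limits what these lists can show: forebrain islands held more reads than lens islands, so a lens region without an island may be below detection. The reads behind scarce fiber transcripts are not known. With equal H3K4me1 lists the forebrain share was 32.9% against 62.5%. Shortening the forebrain list can only lower that share, so the fall does not measure what was missed in lens. Pax6 peaks near genes and the motif at summits were not run. No paired analysis was possible because each group gave 1 list or 1 column, and the replicate numbers of forebrain Pax6 and the inputs are not carried by any value.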

Other observations

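The groups in this part were chosen only after the values were seen, so their medians were not read against random lists. Replication-dependent histone genes were lower in epithelium than in forebrain for 54 of 58 genes (median log2 ratio -2.36), lower in fibers than in forebrain for 57 of 58 (-6.85) and lower in fibers than in epithelium for 54 of 56 (-4.38). These genes share near-identical sequence and their messages lack poly(A) tails, and the libraries were made from total RNA.

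Immediate early genes, which respond within minutes to stimuli including tissue handling, were higher in epithelium than in forebrain for 14 of 14 genes (median 2.45). Fos was listed at 0.291 RPKM in forebrain, 274.3 in epithelium and 7.57 in fibers, Junb at 2.54, 163.8 and 13.3, Egr1 at 0.208, 34.9 and 1.51, and Fosb at 0.0180, 60.1 and 0.534. In fibers against epithelium 12 of 14 were lower (median -2.61), and in fibers against forebrain 5 of 10 were higher and 3 lower (0.98). Ribosomal protein genes had medians of 0.06, 0.48 and 0.49 for epithelium over forebrain, fiber over forebrain and fiber over epithelium, and 70 of 76, 61 of 76 and 60 of 75 genes within 2-fold. In fiber over epithelium 14 genes were higher and 1 lower.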
